A study of Mus musculus with 6 samples.

How the data were processed

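Mouse oviductal epithelial cells were transfected with an empty vector (pCMV-Neo) or a p53 R273H plasmid and selected with antibiotic, per the labels' protocols. Cells were isolated by clonal growth, and RNA was taken at consecutive passages. The number of clones behind each line is not given in the sources used here. The medium held estradiol, serum and growth factors. Total RNA was labelled with biotin by an Affymetrix whole-transcript kit, per the labels.

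The authors deposited log2 expression values for 41345 transcript clusters on 6 arrays. The array model, background correction, summarization and normalization are not given in the sources used here. The values were taken to be log2 because log2 of the authors' deposited ratio matched the difference of group means within 6.64e-05 on every row. The medians of the arrays lay between 4.51 and 4.58. A second deposited table holds the authors' comparison, with a ratio, a signed fold (a score that is minus the inverse below 1), a p-value and a step-up p-value per transcript cluster, per the file headers. The deposited p-value was matched by an unmoderated linear model, and the step-up p-value by Benjamini-Hochberg adjustment over all rows.

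Gene symbols came from the deposited comparison table. Symbols were given for 27032 transcript clusters and not for 14313. A spreadsheet had turned 25 symbols into dates, and 20 were restored through the row's sequence identifier in a RefSeq table of assembly GRCm38.p6. The 828 rows that name several genes and the rows without a symbol were left out. For 1414 genes with several probe sets, the one with the highest mean over all arrays was used. This gave 24252 genes with no filter on dim ones. The deposited files name no genome build, so no coordinates are given. The RefSeq table matched 25895 transcript clusters and served only for names, chromosomes and the order of neighbouring genes.

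Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options, no covariates, two-sided). P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05, and a second count required at least a 2-fold change. Trp53 was also tested by an exact permutation of the 6 arrays. The labels do not say that same-numbered arrays of the groups share a day or passage, so no block entered the main comparison.

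Before the data were examined, 28 gene lists were fixed from general knowledge. They were p53 target genes; epithelial markers; mesenchymal and EMT genes; collagens and matrix proteins; matrix proteases and their inhibitors; integrins and focal adhesion; cell cycle and mitosis; and DNA replication and S phase. Others were cholesterol and mevalonate synthesis, interferon-stimulated genes, antigen presentation, NF-kB targets with cytokines and chemokines, TGF-beta, SMAD and YAP targets, Wnt pathway targets and the Notch pathway. Tissue and stress lists were oviductal secretory and Mullerian duct genes, ovarian cancer markers, motile cilia genes, the NRF2 and xenobiotic response, hypoxia and glycolysis, and endoplasmic reticulum stress and amino acid response. Lists of other origin were fibroblast, smooth muscle, endothelial, leukocyte, and mesothelial and ovarian surface markers, imprinted genes and sex-linked transcripts. Of 570 entries 562 were measured, 8 of them under another symbol, 3 were left out because their row names several genes and 5 were not matched. Ccdc164 is the deposited symbol for Drc1.

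Each list was tested against all other genes with camera (preset correlation 0.01) and Benjamini-Hochberg over the lists, then with an estimated correlation and with fry. Chromosomes with at least 20 genes were tested the same way. A gene counted as expressed if its higher group mean was above the median of all transcript clusters, 4.53. Runs of 41 expressed protein-coding genes in chromosomal order were set against 1000 orders shuffled over all chromosomes together. Biological processes named in the deposited table, with 15 to 300 genes, were tested with camera as well. These terms are cut off in long cells of the deposited table, so some memberships are missing.

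The genes named in the text follow a rule fixed at the same time as the lists. It takes Trp53, Cdkn1a, Mdm2, Cdh1, Cdh2, Vim, Krt8, Pax8, Snai2 and Mki67. It adds the 10 largest rises and 10 largest falls that passed the test with no overlap between groups, leaving out predicted, olfactory, vomeronasal and small RNA genes. It adds, from each list with at least 3 members past the threshold, the 3 largest changes and the largest in the lesser direction, and the brightest member of each list of another cell type. Some genes that this rule picks are not reported here. Genes named outside this rule are said to be so.

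Alternatives were quantile normalization, subtraction of array medians, filters on dim genes at the 30th and 50th percentiles, the mean over a gene's probe sets, a trended and robust variance, no moderation of the variance, a replicate block, and leaving out each array. The thresholds of adjusted p 0.01 and 1.5-fold, all probe sets, an estimated correlation and fry were also run. Random lists matched on mean expression (10000 lists, 20 bins) served as a further comparison. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 in Python 3.11.15.

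The steps were tested on simulated data for the comparison of p53 R273H with empty vector over 24252 genes. Of 100 genes changed by 1 on the log2 scale 97 were recovered, and of 100 changed by 0.5, 20 were recovered. There were 7 false calls among 124. A list of 30 genes shifted by 0.4 was called upward, and 0 other lists of the 28 were. The noise was drawn independently for each gene, and far fewer genes were changed than the 5717 called in the real data. The recovery at 0.5 and the absence of other list calls therefore do not carry over to the real data.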

Results

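The series measured gene expression on 6 arrays of mouse oviductal epithelial (MOE) cells, a line from the mouse counterpart of the fallopian tube. A stable line carrying an empty vector gave 3 arrays, and a stable line carrying a plasmid with the p53 R273H mutant gave 3. R273H replaces an arginine in the DNA-binding domain of p53 and is among the commonest changes of this protein in human tumours. RNA came from consecutive passages of each line. The p-values therefore measure the spread between passages, and line and plasmid cannot be told apart. The number of arrays limits the precision, and the median SD within a group was 0.15 on the log2 scale over 24252 genes.

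The arrays of a group were close to each other. Pearson's r across genes ran from 0.991 to 0.993 within groups and from 0.964 to 0.966 between them, where genes are not independent replicates. The first principal component held 73.8% of the variance and separated the groups. Its scores lay between -42.9 and -42.0 for empty vector and between 41.6 and 43.8 for p53 R273H.

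The signal of Trp53, the mouse gene for p53, was lower in the p53 R273H line (transcript cluster 17251659, chromosome 11). Its mean was 10.06 ± 0.07 (SD, n = 3) with empty vector and 9.39 ± 0.10 (SD, n = 3) with p53 R273H. It fell by 0.68 ± 0.10 (SE) on the log2 scale, with a limma adjusted p of 0.00175. An exact two-sided permutation test of this single gene gave p = 0.1, the smallest that 3 arrays against 3 allow. Probe sequences were not available to tell whether this signal includes the transgene, so it does not check the labels.

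The comparison of the p53 R273H line with the empty vector line asks which genes differ in cells that carry the mutant. Gbp8, a guanylate-binding protein of the interferon-inducible GTPase family, showed the largest measured rise, from 3.32 ± 0.19 to 10.93 ± 0.19 (SD, n = 3 per group), a 195-fold difference. Pgr, the progesterone receptor, rose 73.2-fold, and Snai2, a transcription factor of epithelial-mesenchymal transition, rose 38.0-fold. Serpinb9e, a serine protease inhibitor, showed the largest measured fall, from 10.49 ± 0.10 to 3.74 ± 0.44 (SD, n = 3 per group), a 108-fold difference. C3, the central complement component, was 39.5-fold lower, and Ccl2, a monocyte chemokine, was 31.9-fold lower.

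Among 24252 genes, 5717 changed at a limma adjusted p under 0.05, with 2891 risen and 2826 fallen. At least 2-fold changes were seen for 1337 genes, 619 up and 718 down, and 16 genes rose and 20 fell at least 16-fold. The values of the groups did not overlap for 38.1% of genes, where chance gives 10% for 3 arrays against 3. Without the adjustment, 8150 genes had p under 0.05. At adjusted p under 0.01 the count was 3576, and at least 1.5-fold changes numbered 3221.

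The other genes with the largest rises on the log2 scale were Trdn (5.72 ± 0.24 SE), the phosphodiesterase Pde7b (5.33 ± 0.09), Gbp11 (4.96 ± 0.17), Pmp2 (4.93 ± 0.11), the urea transporter Slc14a1 (4.77 ± 0.11), the growth factor Gdf6 (4.77 ± 0.14) and the proteoglycan Dcn (4.70 ± 0.10). The other large falls were in Entpd5, which fell by 5.22 ± 0.11, Cyp4a12b, which fell by 4.99 ± 0.15, and the vitamin D binding protein Gc, which fell by 4.97 ± 0.15. Havcr1 fell by 4.96 ± 0.16, the chemokine Cxcl3 fell by 4.87 ± 0.23, Ly6a fell by 4.78 ± 0.17 and the costimulatory molecule Cd80 fell by 4.77 ± 0.10. For Gbp8, Pgr, Trdn, Pde7b, Snai2, Gbp11, Pmp2, Gdf6, Dcn, Serpinb9e, Entpd5, Ccl2, Gc and Cxcl3 the lower group mean was under 4.53, the median of all transcript clusters. The files do not say whether such signals exceed background, so the folds of these genes are not exact. Gbp8, Gbp11, Gc and Cxcl3 lie on chromosome 5, where expressed genes had a median log2 fold change of 0.46.

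**Figure D1:**
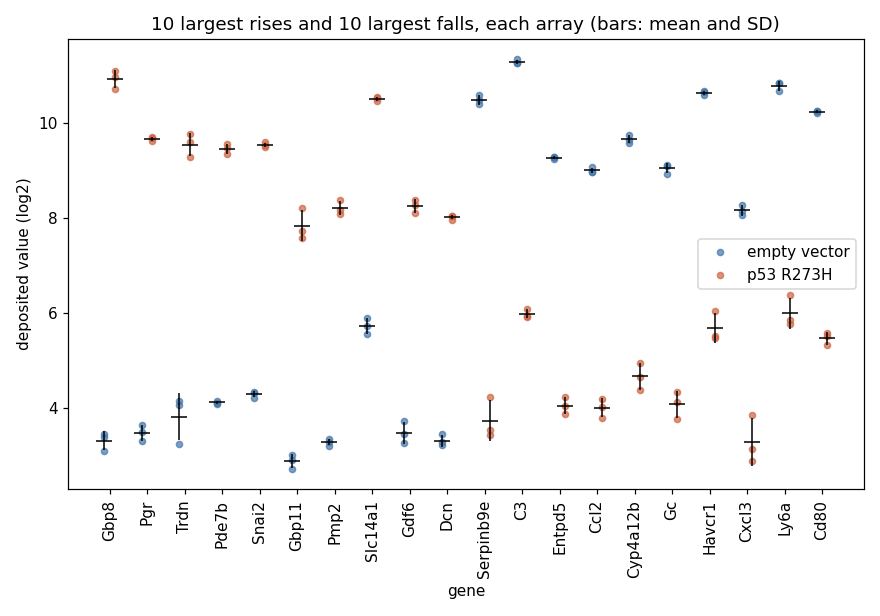
Deposited log2 value of each array (points) for the 10 genes with the largest rise and the 10 with the largest fall, with the mean and SD of the 3 arrays of a group as bars. Gbp8 went from a mean of 3.32 with empty vector to 10.93 with p53 R273H, and Serpinb9e from 10.49 to 3.74.

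Genes that p53 is known to activate were mostly lower in the p53 R273H line. Of 30 measured p53 target genes, 19 fell, 2 rose and 9 did not pass the test, and adjusted over the list alone 22 fell and 3 rose. Trp53inp1, a p53-induced stress protein, fell by 2.26 ± 0.11 (SE) on the log2 scale. Ddit4, an inhibitor of mTOR signalling, fell by 1.71 ± 0.10, and the kinase Plk2 fell by 1.36 ± 0.09. Mdm2, the ubiquitin ligase of p53, fell by 0.50 ± 0.09 (adjusted p = 0.00484). Plk3 rose by 0.83 ± 0.11. The cell cycle inhibitor Cdkn1a did not pass the test, at -0.18 ± 0.11 (adjusted p = 0.31). The list's median was -0.46, and camera called it lower than other genes (adjusted p = 5.89e-07), a call that did not hold with an estimated correlation (adjusted p = 0.07 with an estimated correlation).

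**Figure D2:**
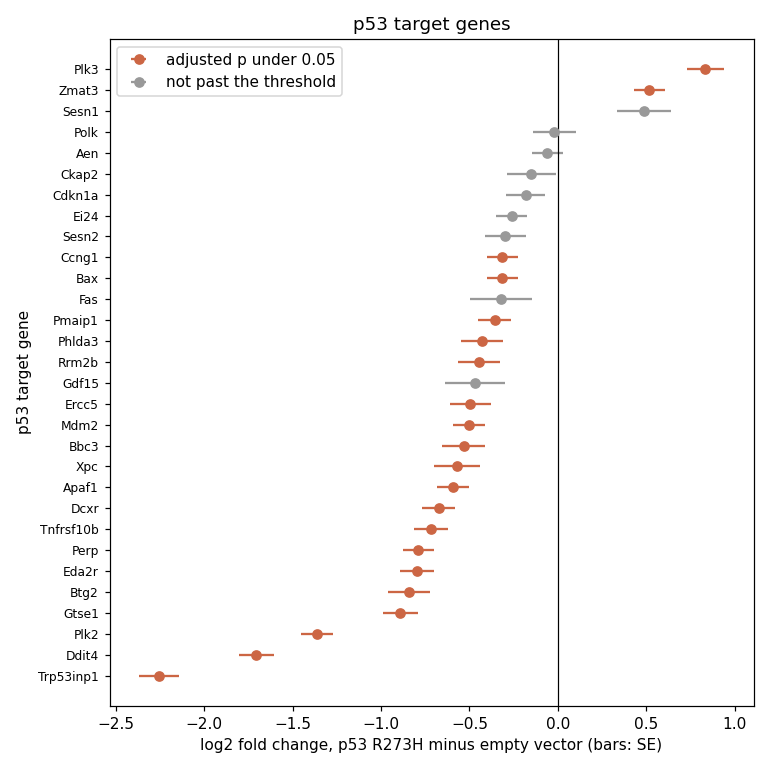
Log2 fold change (p53 R273H minus empty vector, 3 arrays per group) of each of the 30 p53 target genes, with its SE, coloured by whether it passed an adjusted p of 0.05. Of the 30 genes 19 fell, and Trp53inp1 had the lowest value at -2.26.

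Inflammatory genes formed the list with the lowest median. Of 27 NF-kB targets, cytokines and chemokines, 16 fell and 5 rose, the same numbers adjusted over the list alone. Ccl2 fell by 4.99 ± 0.12 on the log2 scale, and among adhesion molecules Icam1 fell by 3.56 ± 0.18 and Vcam1 fell by 3.54 ± 0.09. Nfkbia, the inhibitor of NF-kB, rose by 1.13 ± 0.09. The list's median was -0.51, with a camera adjusted p of 7.95e-05 (adjusted p = 0.07 with an estimated correlation). Of 17 antigen presentation genes 6 fell and 0 rose, also when adjusted over the list alone. The class I gene H2-K1 fell by 1.40 ± 0.11, Cd74 fell by 1.28 ± 0.12 and the peptide transporter Tap1 fell by 0.99 ± 0.13. Camera called this list lower (adjusted p = 0.00857), but not with an estimated correlation (adjusted p = 0.145 with an estimated correlation). Of 25 interferon-stimulated genes, 3 rose and 2 fell, also over the list alone. Xaf1 rose by 1.35 ± 0.10 and Ifit2 by 1.09 ± 0.09, and Oasl2 fell by 0.57 ± 0.13, a call lost under some alternatives. Camera did not call this list (adjusted p = 0.508).

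Genes linked to TGF-beta signalling mostly rose, and mesenchymal genes that passed the test rose more often than they fell. Of 20 TGF-beta, SMAD and YAP targets 14 rose and 2 fell, and adjusted over the list alone 14 rose and 3 fell. The matrix protein Tgfbi rose by 3.74 ± 0.11 on the log2 scale, the ligand Tgfb3 by 2.70 ± 0.09 and the latency protein Ltbp1 by 1.90 ± 0.09, and Id2 fell by 0.65 ± 0.12. The median was 0.57, with a camera adjusted p of 2.7e-05 (adjusted p = 0.07 with an estimated correlation).

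Of 20 mesenchymal and EMT genes 9 rose and 2 fell, also over the list alone. Snai2 rose from 4.29 ± 0.06 to 9.54 ± 0.05 (SD, n = 3 per group). Smooth muscle actin Acta2 rose by 1.82 ± 0.10, tenascin Tnc by 1.40 ± 0.11 and vimentin Vim by 0.45 ± 0.09. The lysyl oxidase Loxl2 fell by 1.35 ± 0.10 and N-cadherin Cdh2 fell by 0.54 ± 0.09. The median was 0.22, with a camera adjusted p of 0.0229 (adjusted p = 0.145 with an estimated correlation). Without p53 R273H replicate 2 the camera adjusted p was 0.0536.

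Of 26 collagens and matrix proteins, 10 rose and 5 fell, and 12 rose and 6 fell adjusted over the list alone. Dcn rose by 4.70 ± 0.10 and Col6a2 by 2.54 ± 0.12, while the laminin Lama5 fell by 2.53 ± 0.09. The camera adjusted p was 0.0463 (adjusted p = 0.281 with an estimated correlation). It was 0.0873 without p53 R273H replicate 1, 0.0552 without p53 R273H replicate 3, and 0.0512 and 0.0508 without empty vector replicates 2 and 3.

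Epithelial markers went both ways. Of 20 genes 6 fell and 2 rose, and 7 fell and 3 rose adjusted over the list alone. The keratin Krt19 fell by 2.50 ± 0.09, the keratin Krt8 fell by 1.19 ± 0.10, the protease St14 fell by 1.98 ± 0.13, and the transcription factor Elf3 rose by 2.15 ± 0.11. E-cadherin Cdh1 did not pass the test, at 0.19 ± 0.10 (adjusted p = 0.228), with means of 5.04 with empty vector and 5.23 with p53 R273H. Camera did not call the list (adjusted p = 0.163). Epcam, Esrp1, Ocln, Cldn7 and Rab25, named outside the rule, had means under 4.53, the median of all transcript clusters, in both groups. A fall of such dim genes could be missed, so the list does not show that epithelial expression was kept. Of 25 matrix proteases and their inhibitors 8 rose and 6 fell, also over the list alone. Mmp2 rose by 1.53 ± 0.09 and Mmp9 fell by 1.33 ± 0.17. The list's median was -0.04, its mean was 0.08, and camera gave an adjusted p of 0.735 in the upward direction. Of 23 integrins and focal adhesion genes 9 rose and 5 fell, and 11 rose and 7 fell over the list alone. Itga1 was 2.83-fold lower, Itgb8 fell by 1.29 ± 0.16 and Itgb4 rose by 1.39 ± 0.16, with a camera adjusted p of 0.264.

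Markers of the oviduct went both ways, with rises in hormone receptors. Of 19 oviductal secretory and Mullerian duct genes 5 rose and 4 fell, and 6 rose and 4 fell adjusted over the list alone. Pgr rose from 3.48 ± 0.17 to 9.67 ± 0.04 and the estrogen receptor Esr1 from 4.52 ± 0.28 to 8.13 ± 0.06 (SD, n = 3 per group). Wt1 fell by 1.93 ± 0.10 on the log2 scale. The secretory lineage factor Pax8 had a difference of 0.27 ± 0.09 that did not pass the test (adjusted p = 0.0598). Camera did not call this list (adjusted p = 0.508). Of 19 ovarian cancer markers 6 fell and 1 rose, also over the list alone. Mal fell by 3.73 ± 0.20, the protease inhibitor Slpi fell by 2.99 ± 0.12 and Crabp2 fell by 1.11 ± 0.15, and Mecom rose by 0.58 ± 0.13. Camera called this list lower (adjusted p = 0.00372), but not with an estimated correlation (adjusted p = 0.145 with an estimated correlation). Of 24 motile cilia genes 5 rose and 1 fell, also over the list alone. Tekt2 rose by 1.03 ± 0.10 and Ccdc164, on chromosome 5, by 0.83 ± 0.14, while the ciliogenesis factor Foxj1 fell by 0.88 ± 0.11. Camera did not call the cilia list (adjusted p = 0.264).

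Of 22 Wnt pathway targets 9 fell and 2 rose, also over the list alone. The ligand Wnt4 fell by 3.29 ± 0.09 on the log2 scale, Wisp1 fell by 3.01 ± 0.09, the transcription factor Lef1 fell by 2.33 ± 0.14 and Sp5 rose by 1.03 ± 0.15. Wisp1 lies on chromosome 15, where the median of expressed genes was -0.40. The camera adjusted p of the list was 0.00139 (adjusted p = 0.145 with an estimated correlation). Of 16 Notch pathway genes 4 rose and 3 fell, and 6 rose and 3 fell over the list alone. Notch1 fell by 1.16 ± 0.11, Nrarp fell by 0.73 ± 0.12 and Hey2 rose by 1.04 ± 0.10, with a camera adjusted p of 0.682.

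Proliferation genes went both ways. The proliferation marker Mki67 was at 9.80 ± 0.08 with empty vector and 9.79 ± 0.04 with p53 R273H (SD, n = 3 per group), and its difference of -0.01 ± 0.09 did not pass the test (adjusted p = 0.963). Of 25 cell cycle and mitosis genes 7 rose and 2 fell, also over the list alone. Foxm1 rose by 0.68 ± 0.11 and Bub1b by 0.63 ± 0.11, and Kif23 fell by 0.68 ± 0.09. For this list camera gave an adjusted p of 0.0738, and 0.035 with a trended and robust variance (adjusted p = 0.456 with an estimated correlation). Of 23 DNA replication and S phase genes 5 rose and 3 fell, also over the list alone. Rrm2 rose by 1.06 ± 0.09, Ccne1 by 0.83 ± 0.12 and E2f1 by 0.74 ± 0.13. Camera did not call the replication list (adjusted p = 0.682).

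Stress and metabolic lists moved in different directions. Of 21 NRF2 and xenobiotic response genes 9 fell and 4 rose, and 10 fell and 5 rose adjusted over the list alone. Among glutathione transferases, Gsta4 fell by 3.83 ± 0.13, Gsta3 fell by 3.13 ± 0.24 and Gsta1 fell by 1.27 ± 0.23, while Akr1c18 rose by 1.10 ± 0.16. Gsta1 to Gsta4 are similar in sequence, and shared hybridization between them was not tested. The camera adjusted p was 0.0244 (adjusted p = 0.145 with an estimated correlation), and 0.0587 once dim genes under the 30th percentile were left out. Of 23 hypoxia and glycolysis genes 10 rose and 2 fell, and 11 rose and 3 fell over the list alone. The peptide hormone gene Adm rose by 4.63 ± 0.10 and P4ha2 by 0.88 ± 0.10, and Ndrg1, on chromosome 15, fell by 1.94 ± 0.09. The camera adjusted p was 0.0229 (adjusted p = 0.145 with an estimated correlation). Of 20 genes of endoplasmic reticulum stress and amino acid response 9 rose and 1 fell, and 12 rose and 2 fell over the list alone. Chac1 rose by 1.64 ± 0.13, Xbp1 by 0.89 ± 0.09 and Trib3 by 0.74 ± 0.10, and Asns fell by 0.40 ± 0.12, a call lost under most alternatives. For this list camera gave 0.00372 as adjusted p (adjusted p = 0.145 with an estimated correlation).

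Of 24 genes of cholesterol and mevalonate synthesis 8 rose and 7 fell, and 10 rose and 8 fell over the list alone. Mvk rose by 1.03 ± 0.09, while the regulator Srebf2, on chromosome 15, fell by 1.01 ± 0.08. The list's median was -0.15 and its mean 0.06, and camera gave an adjusted p of 0.898 in the upward direction.

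Markers of cell types other than the oviductal epithelium were measured too. Of 15 fibroblast markers 3 rose and 3 fell, also over the list alone. Dcn rose and Ly6a, the brightest member, fell, as did Cd34, which fell by 2.31 ± 0.18. The list's median was 0.05 and its mean -0.05, and the camera adjusted p was 0.833. Of 11 smooth muscle markers 2 rose and 1 fell, also over the list alone. Acta2 was the brightest, Tagln rose by 0.60 ± 0.14 and Cnn1 fell by 0.86 ± 0.11 (camera adjusted p = 0.712). Of 13 endothelial markers 2 rose and 1 fell, also over the list alone. The receptors Kdr, the brightest, and Flt1, both on chromosome 5, rose by 1.76 ± 0.10 and by 1.41 ± 0.09, and Tie1 fell by 0.35 ± 0.10, a call lost under most alternatives (camera adjusted p = 0.264). Of 15 leukocyte markers 2 rose and 1 fell, and 3 rose and 1 fell over the list alone. Cd14, the brightest, rose by 0.42 ± 0.10 and Ptprc by 0.60 ± 0.13, and Cd68 fell by 0.73 ± 0.09 (camera adjusted p = 0.508). Ptprc and Tie1 had means under 4.53, the median of all transcript clusters, in both groups. Whether their signals exceed background is unknown.

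Of 13 mesothelial and ovarian surface markers 6 fell and 2 rose, and 6 fell and 3 rose over the list alone. The retinoic acid enzyme Aldh1a2 fell by 3.39 ± 0.11, Podxl fell by 2.46 ± 0.13 and Msln, the brightest, fell by 0.92 ± 0.09. Upk3b, on chromosome 5, rose by 1.00 ± 0.17. The camera adjusted p was 0.00857 (adjusted p = 0.145 with an estimated correlation). Among other members, this list shares Krt19 with the epithelial markers, Msln with the ovarian cancer markers and Wt1 with the oviductal genes.

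Of 21 imprinted genes 5 rose and 3 fell, also over the list alone. Peg3 fell by 3.76 ± 0.10 and Sgce fell by 2.48 ± 0.12, and Grb10 rose by 1.89 ± 0.15. The median was -0.02 and the mean -0.10, while camera gave an adjusted p of 0.898 in the upward direction. Of 5 sex-linked transcripts Xist, which silences an X chromosome and is named after its value was seen, fell by 1.26 ± 0.08, and the other 4 did not pass the test, also over the list alone (camera adjusted p = 0.618).

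Camera, with a preset correlation, called 12 of the 28 lists, 7 lower and 5 higher, and 0 were called with an estimated correlation (9 had an unadjusted p under 0.05). Fry, which tests whether the genes of a list move on balance one way and compares them with no other genes, called 23 lists. Its mixed test of change in either direction called 28. The single-gene calls of Mecom, Ccdc164, Gsta1, Tagln, Cd14 and Upk3b were also lost under at least 1 alternative.

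**Figure D3:**
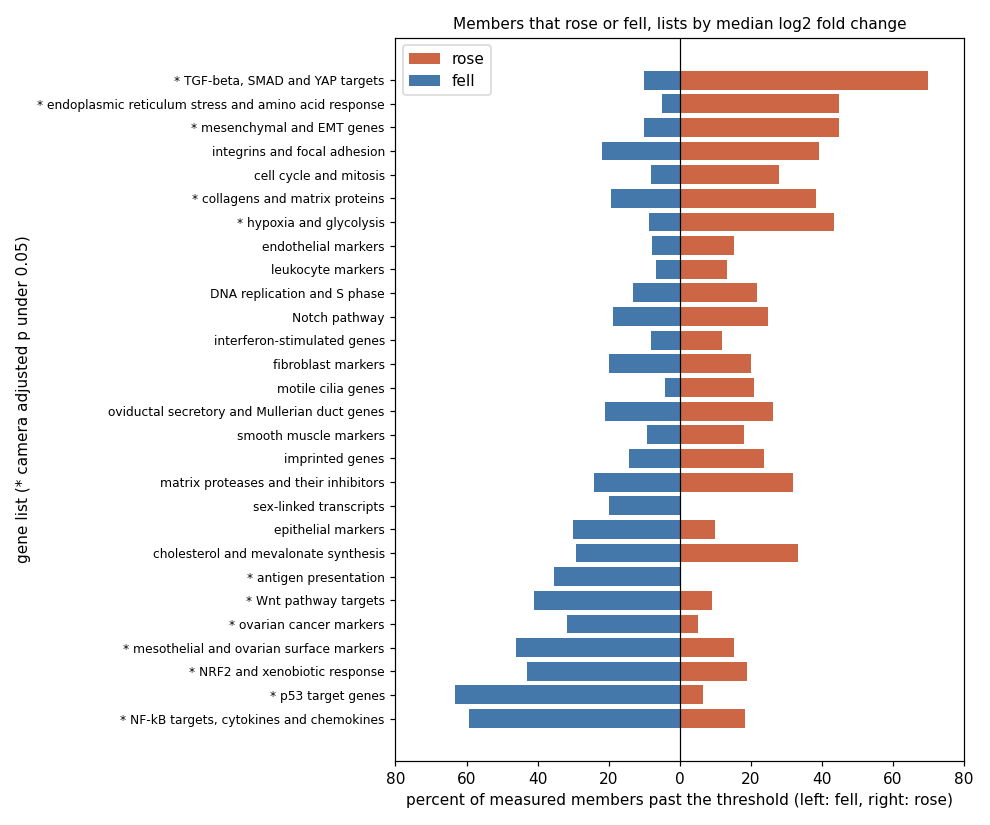
Percent of the measured members of each of the 28 gene lists that rose (right) or fell (left) at adjusted p under 0.05, ordered by the list's median log2 fold change, with an asterisk for a camera adjusted p under 0.05. Of the TGF-beta, SMAD and YAP targets 14 of 20 rose, and of the p53 target genes 19 of 30 fell.

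The median of expressed genes was shifted on some chromosomes. On chromosome 5, 523 of 926 expressed genes rose and 44 fell, with a median log2 fold change of 0.46. On chromosome 15, 318 of 599 fell and 24 rose, with a median of -0.40. The medians of chromosomes X, 14 and 2 were -0.30, -0.28 and 0.15. Camera called these 5 chromosomes, with adjusted p-values of 2.33e-12 for chromosome 5 and 5.58e-11 for chromosome 15. They were called with an estimated correlation as well, where the number of chromosomes called was 10. Of the named genes, Mvk, Oasl2, Kdr, Flt1, Ccdc164 and Upk3b also lie on chromosome 5, and Krt8, Ly6a, Wisp1, Ndrg1 and Srebf2 on chromosome 15. On each array of a group, the expressed genes of chromosomes 5 and 15 deviated to the same side.

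**Figure D4:**
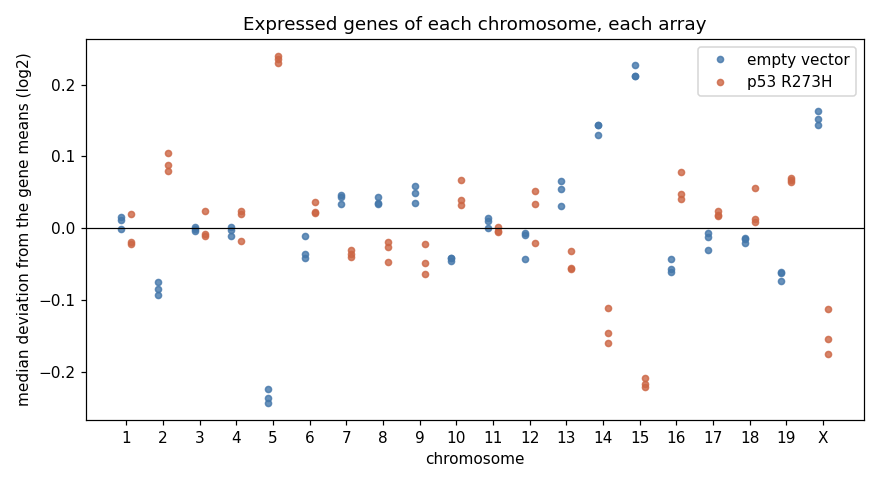
Median deviation (log2) of the expressed genes of each chromosome from each gene's mean over the 6 arrays, 1 point per array. On chromosome 5 the 3 p53 R273H arrays sit between 0.23 and 0.24 and the 3 empty vector arrays between -0.24 and -0.22.

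The authors' deposited table of the same comparison lists 5317 of 41345 transcript clusters with a step-up p under 0.05, 2599 higher and 2718 lower with the mutant. In the authors' deposited table, 722 of them were at least 2-fold higher and 984 at least 2-fold lower. Across transcript clusters, its log2 ratios and the differences of group means computed here had a Pearson's r of 1, also above the median expression, since both come from the same values.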

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

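The tests of a general interferon response, of a copy gain as the whole cause of the Gbp rise, and of a difference between lines were chosen after the values were seen, as was the removal of chromosome medians. The other tests of this part were written down before they were run. Those on the Gbp genes took up a rise already seen. The interval used for the copy gain around these genes was not part of its written rule.

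Of 14313 probe sets without a gene symbol, which the results per gene leave out, 1165 changed at a limma adjusted p under 0.05. Of these 431 rose and 734 fell, and they make up 8.14% against 18.2% of probe sets with 1 gene.

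The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 5717 genes at a limma adjusted p under 0.05 and the highest of the others gave 0, with at most 713 genes at an unadjusted p under 0.05. For at least 2-fold changes the real split gave 1337 and the highest of the others 0. In both cases 1 of the 10 splits, the real one, gave as many genes. Every other split mixes arrays of both lines, so the difference between lines enters the spread within its groups. The low counts of those splits follow from this mixing and say nothing about chance.

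For the fall of the p53 target genes, 0 of 10000 random lists of the same size matched on mean expression had a median as low as -0.46, the lowest being -0.34, which argues against a trend with expression level left by the normalization. The highest number of fallen members in any of them was 16 against 19 in the list, which argues against drift blind to membership. With the median of each chromosome's expressed genes removed from all its genes, the list's camera adjusted p was 4.85e-06. This removal can shift dim genes, with which camera compares the list, the other way. The call did not hold in the unaltered data with an estimated correlation (adjusted p = 0.07 with an estimated correlation). The random lists take no account of correlation between members either. A difference between the lines that is not due to R273H cannot be told apart from an effect of the mutant, since each group has 1 source label.

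The Gbp genes of chromosome 5 rose together, with 6 of 6 past the test and a median log2 fold change of 4.30, while 0 of 5 on chromosome 3 passed it; the interferon-stimulated list, of which 12% rose, argues against a general interferon response. The 12 expressed neighbours within 1 Mb had a median of 0.29 (95% interval 0.02 to 1.08). This interval includes the 0.46 of expressed genes on chromosome 5. Of these neighbours 6 rose and 1 fell. The largest rises were in Lrrc8c at 2.77, Lrrc8b at 1.14 and Pkd2 at 1.08, all named outside the rule. The rule written down for a copy gain looked at the median alone, which lies just under its limit for no gain. The interval was not part of that rule. It reaches past the limit set for a gain, so the median is taken to decide neither. A gain that reaches most of these neighbours is argued against as the whole cause, because the upper bound of 1.08 is far below the Gbp median. A gain confined to the cluster, or one that reaches only some neighbours, stays open. Hybridization shared between similar Gbp transcripts may contribute too: without probe sequences it is open how many of the 6 rose, and the highest value on chromosome 3, Gbp3 (named outside the rule) at 0.49, does not settle it.

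For the rise of mesenchymal and TGF-beta related genes, fibroblasts in the p53 R273H cultures would bring Col1a1, Col1a2 and Col3a1 (named outside the rule, for this test) together, yet Col1a1 rose by 0.72, Col3a1 was at -0.11 and Col1a2 had the lowest value at -1.04. Of 10000 random lists matched on mean expression 0 had a median as high as the 0.44 of the 40 genes of both lists, the highest being 0.31, which argues against a trend with expression level for the pooled genes only. The TGF-beta list carries this value, with a median of 0.57, and the mesenchymal list, with 0.22, was not tested alone. Camera calls neither list with an estimated correlation (adjusted p = 0.07 and 0.145 with an estimated correlation). A difference between the lines apart from R273H stays open here too.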

How the results depend on the processing

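The setting that removes each chromosome's median, and the chromosome counts beyond the estimated correlation and the median filter, were chosen after seeing the data. Unmoderated variances were not run for the lists and chromosomes, because camera moderates its own. Trp53 kept its direction and call, from -0.73 to -0.63 over the settings. Changed genes numbered 4420 to 4869 and 2-fold changes 1331 to 1374 with 1 array left out. At adjusted p under 0.01 there were 3576 changed genes, 1795 risen and 1781 fallen, and at least 1.5-fold 3221, 1597 risen and 1624 fallen, as looser or stricter limits give by construction. The balance of risen and fallen genes depends on scaling: 3113 rose and 2764 fell with quantile normalization, and 3281 rose and 2535 fell with array medians subtracted. With chromosome medians removed, 5726 genes changed and 1203 at least 2-fold. The median of a chromosome's expressed genes was taken from all its genes, dim ones included. On chromosome 5 this median was 0.46, while the median of all its genes was 0.25. The removal can thus shift dim genes the other way, so these counts do not show how far the chromosome shifts matter. Same-numbered arrays deviated with correlations of -0.07, 0.01 and 0.00, so no shared deviation was seen. Such values cannot show whether a number marks the same passage or day in both lines. With the replicate block 4826 genes changed, 1336 at least 2-fold, and the collagen list's adjusted p was 0.0505.

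Of the 28 lists, 24 kept their side of the threshold under 14 settings, the estimated correlation and fry apart. The 9 called lists among them also kept their direction, which was not checked for the 15 that were not called. Mesenchymal and EMT genes ranged from 0.0104 to 0.0536 with 1 array left out, the highest without p53 R273H replicate 2. Collagens and matrix proteins ranged from 0.0332 to 0.0873 with 1 array left out, and gave 0.0619 with array medians subtracted and 0.0587 and 0.0924 with dim genes under the 30th percentile and the median left out. NRF2 genes gave 0.0587 and 0.118 with the same filters, and cell cycle genes 0.035 with a trended and robust variance (0.456 with an estimated correlation). The cause was not tested.

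With an estimated correlation the adjusted p was 0.07 for the p53, NF-kB and TGF-beta lists, 0.281 for collagens and 0.145 for the other 8 called lists (mesenchymal, antigen presentation, Wnt, ovarian cancer, NRF2, hypoxia, endoplasmic reticulum stress, mesothelial). The cause was not tested. The number of chromosomes called was then 10 against 5. Fry, which asks another question, gave adjusted p-values of 0.000306 for epithelial markers, 0.000679 for proteases, 0.00911 for integrins, 0.00971 for cell cycle, 0.0371 for cholesterol, 0.0082 for interferon, 0.000325 for oviductal, 0.0176 for cilia, 0.00102 for endothelial and 0.0377 for sex-linked genes. For imprinted genes it gave 0.00971 downward, where camera pointed up without a call.

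For 112 genes picked by the naming rule other than Trp53 there were 1678 values under the alternatives. Of these values 1638 kept their side of the threshold, 35 lost the call and 5 gained it. With a call in the main analysis or the alternative, 0 turned direction. A turn between values without a call was not counted. The 35 losses fell in 10 genes, among them Oasl2, Mecom, Ccdc164, Gsta1, Asns, Tagln, Tie1, Cd14 and Upk3b, and the 5 gains were all in Pax8. With chromosome medians removed the adjusted p was 0.0935 for Ccdc164 and 0.0545 for Upk3b. The files give no background value or detection call, so how far dim genes exceed background is unknown.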

Other observations

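The tests of biological processes and of runs of neighbouring genes, and the genes named here outside the rule, were chosen after the values were seen. The estrogen and chromosome tests were written down before they were run, but the estrogen test took up a rise of Esr1, Pgr and Greb1 already seen.

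Of 18 genes annotated to inactivation of MAPK activity, 10 rose and 2 fell, with Spred2 at 1.60, Spred1 at 1.38, Dusp2 at 1.05 and Dusp1 at 1.03 on the log2 scale, against Dusp9 at -0.54 and Dusp4 at -0.40. Of 17 genes of cartilage condensation 8 rose and 0 fell, led by Sox9 at 2.22 and Mycn at 1.77. Of 16 genes of neutrophil chemotaxis 7 fell and 0 rose, with Cxcl3 at -4.87 and Cxcl1 at -1.30. Of 91 genes of rRNA processing 27 fell and 9 rose, with Dis3 at -1.26 and Bop1 at -0.76. Camera called these 4 of 539 processes (adjusted p = 0.0464 for each). With an estimated correlation it called 0 (adjusted p = 0.944 for each).

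Esr1, Pgr and Greb1, an estrogen receptor cofactor named outside the rule, rose by 3.61 ± 0.15, 6.19 ± 0.11 and 4.68 ± 0.17 (SE). The medium of both lines held estradiol. A hypothesis was that estrogen-responsive genes rose more widely. Of 24 others 3 rose and 5 fell, and 5 rose and 5 fell adjusted over the list alone. Sgk1 at 2.64, Fos at 1.68 and Xbp1 at 0.89 rose, while Stc2 at -2.19 and Igf1 at -0.79 fell. With 12.5% risen, the hypothesis of a wider rise was not borne out for these 24 genes. Of all 24252 genes, 2891 rose. Dim genes were not left out, and whether the 24 respond to estrogen in oviductal cells was not tested. An estrogen response of other genes therefore stays open.

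Chromosomes 5, 14, 15 and X, 4 in all, had a median of expressed genes beyond 0.25 in size and a camera call. A copy number difference between the lines is a candidate explanation, since gene dosage moves neighbouring genes alike. On chromosome 5 even the lowest run of 41 neighbouring genes had a median of 0.23. On chromosomes 14, 15 and X even the highest runs had medians below 0, of -0.01, -0.08 and -0.08. In these runs 12, 15 and 15 genes fell and 3, 5 and 3 rose. The highest of many runs lies above a chromosome's median even where all its genes shift alike. These values therefore do not decide whether the shift there runs along the whole chromosome. On chromosome 15 the run from Sepp1 to Zfp622 had a median of -0.86, with 32 of 41 genes fallen, and on chromosome 2 the run from Rif1 to Fastkd1 reached 0.67. The largest run median over 1000 shuffled gene orders was 0.45 in size. The shuffles moved genes between chromosomes and so removed whole-chromosome shifts as well. They cannot tell a shift of part of chromosome 15 or 2 from a shift of the whole chromosome. DNA was not measured here, and the arrays cannot show which line departs from the parental cells. On the X chromosome, Xist, named outside the rule, fell by 1.26 ± 0.08 (SE).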
